A study of Homo sapiens with 6 samples.

How the data were processed

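Total RNA was extracted from the cells with a miRNeasy kit, and biotin-labelled target was prepared from 1 µg of it, per the labels' protocols. The labels' protocols name a whole-transcript terminal labelling kit, while the array type that the series names is a 3' expression array. The cells grew in medium with 10% serum, and the transduced cells were kept in 0.5 µg/ml puromycin. The deposited values are log2 expression values, 1 per probe set and array, made with RMA per the submitters' processing notes. RMA corrects background, normalises arrays together by quantiles and summarises the probes of a probe set, and its version and annotation are not given in the sources used here. The values were used as deposited, with no scanner output.

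The table holds 54675 probe sets, of which 62 are control probe sets that were left out of all tests. In the platform annotation 41097 probe sets have 1 gene symbol, 1801 have several and 11777 have none. Symbols were set against a reference table through gene identifiers, which 41043 of those with 1 symbol matched, and 0 symbols changed. A gene was represented by the probe set of its own with the highest mean over the 6 arrays, which left 19775 genes. No filter on dim genes was applied. Probe sets with several symbols or none, 13522 in all, were tested only by identifier. Array medians over all probe sets ran from 5.60 to 5.67, no pair of arrays held identical values, and the 3' minus 5' difference of the control probe sets for GAPDH ran from -0.046 to -0.0084. For ACTB it ran from 0.21 to 0.30. In a principal component analysis of the genes the first component (46.1% of the variance) parted the groups and the second (21.6%) set S153E-RKIP replicate 1 apart from replicates 2 and 3 of its group.

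Groups were taken from the sample titles. The 3 arrays labelled S153E-RKIP were compared with the 3 control arrays in limma 3.58.1 under R 4.3.3, with a linear model for each gene (lmFit, eBayes without trend, two-sided) and Benjamini-Hochberg adjustment over all genes. A gene was called at an adjusted p under 0.05. Standard errors and 95% confidence intervals of single genes come from the moderated variance. The standard error of a list mean is the SD over its members divided by the square root of their number. It takes the members as independent and does not measure the spread between arrays. At an unadjusted p under 0.05 there were 3098 genes. Each of the 26 gene lists was tested with camera at its preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. The lists hold 576 distinct genes, of which 530 were measured by a probe set of their own. For each list, 10000 random lists of the same size matched on mean expression in 40 bins were also drawn. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule names PEBP1, HMGA2, LOX, SDC2 and DUSP6 always. It adds the 8 largest rises and 8 largest falls among called genes whose groups do not overlap, whose higher group mean exceeds the median of all genes (6.64) and which have an official symbol. For each list past the set test or with at least 3 called members it adds up to 4 called members with the smallest p, and for other lists the called member with the smallest p. It gave 47 genes.

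The fit was tested on simulated data for the comparison of S153E-RKIP with control, drawn for 19775 genes from their means and variances, with 200 genes changed by known amounts. Of 50 genes changed 1.3-fold, 40 were recovered, as were all 50 at each of 1.5-fold, 2-fold and 4-fold, and 6 of 19555 unchanged genes were called. Of 26 simulated lists only the 1 that was shifted by 0.3 passed camera. The simulated genes were drawn independently, while the estimated correlation was 0.13 in the NF-kB list and 0.22 in the cholesterol synthesis list. The simulation therefore does not test camera at its preset correlation on correlated genes. The alternatives were the mean of a gene's probe sets, each probe set by itself, no probe sets ending in _x_at, both dim-gene filters, quantile normalisation again, equal medians, eBayes with trend and robust estimation, array weights, a replicate block, a stricter threshold, and each array left out in turn. Removal of the intensity trend of the difference by loess was added after seeing the data. Figures were drawn with matplotlib 3.10.9.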

Results

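Transcript levels were measured on 6 Affymetrix HG-U133 Plus 2.0 arrays, 3 for control cells and 3 for cells labelled as expressing S153E-RKIP. The cells are the 1833 subline of the MDA-MB-231 human breast cancer line, a subline known for growing in bone. RKIP, encoded by PEBP1, is a protein that binds Raf-1 and restrains signalling to MEK and ERK. S153E-RKIP is a mutant form that the series describes as the stronger inhibitor of Raf-1. It was introduced with a lentiviral vector under puromycin selection, and the control carried the vector. The labels call the 3 samples of each group biological replicates without saying how they were made, so the p-values measure the spread between these samples, which may be partly technical. The number of arrays limits the precision, and the median standard error of a log2 fold change over the 19775 genes was 0.072. All values are log2 RMA signals, and all differences are S153E-RKIP minus control.

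The transcript of the introduced gene was measured first, as a check of the labels. PEBP1 had a level of 11.77, 11.73 and 11.77 in control replicates 1, 2 and 3, and of 11.74, 11.64 and 11.61 in S153E-RKIP replicates 1, 2 and 3. The difference was -0.093 (SE 0.058, 95% confidence interval -0.23 to 0.040, limma adjusted p = 0.473). All 3 probe sets of PEBP1 had a difference below 0, and none passed the threshold or had an unadjusted p under 0.05. Whether these probe sets lie within the introduced sequence is not given in the sources used here, so PEBP1 neither bears out nor contradicts the labels if they lie outside it. The source name of the treated samples speaks of shRNA against HMGA2, while their title, description and characteristics speak of S153E-RKIP. HMGA2, a chromatin protein gene repressed by let-7, had a level of 9.79 ± 0.019 (SD, n = 3) in control and 9.77 ± 0.066 (SD, n = 3) in the other group. Its difference was -0.023 (SE 0.058, 95% confidence interval -0.16 to 0.11, adjusted p = 0.882). None of its 9 probe sets passed the threshold, and 1 had an unadjusted p under 0.05. Because neither gene went with a label, the treated samples are called the arrays labelled S153E-RKIP, and every direction below rests on that label.

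**Figure D1:**
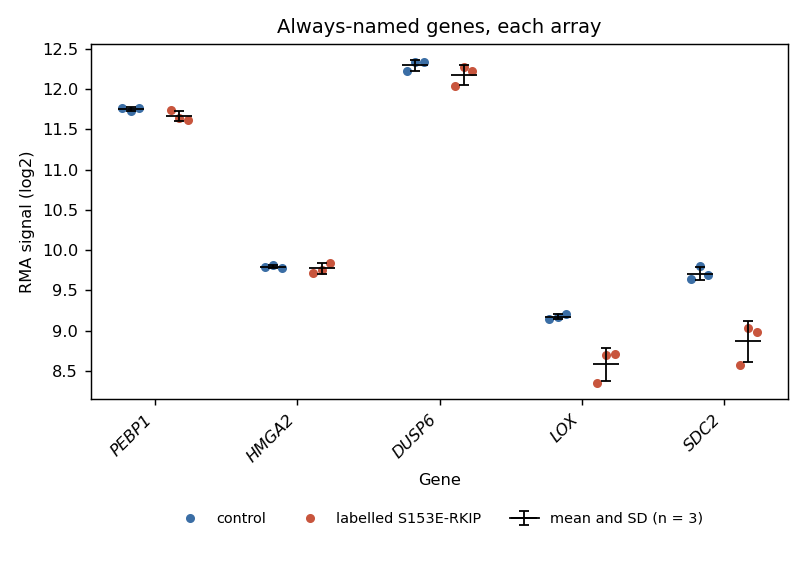
RMA signal (log2) of PEBP1, HMGA2, DUSP6, LOX and SDC2 on each control array and each array labelled S153E-RKIP, with the mean and SD of the 3 arrays of a group. LOX and SDC2 lie lower on all 3 arrays labelled S153E-RKIP than on any control array, while the arrays of both groups overlap for HMGA2, PEBP1 and DUSP6.

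The comparison asks which genes RKIP regulates in these breast cancer cells. On the arrays labelled S153E-RKIP, 12 of 20 measured NF-kB target genes rose and 12 of 17 cholesterol synthesis genes fell. Both lists passed the set test, a call lost with an estimated correlation (adjusted p = 0.0696 for each) and kept by fry (adjusted p = 7.57e-04 for each). Among genes with a probe set of their own, the largest fitted rise was that of BCL2A1, an NF-kB target that protects cells from apoptosis, from 5.60 ± 0.12 to 9.04 ± 0.12 (SD, n = 3 each), or 10.9-fold. The largest fall among them was that of SCD, the desaturase that makes monounsaturated fatty acids, from 11.37 ± 0.17 to 8.45 ± 0.41 (SD, n = 3 each), or 7.57-fold. In all, 136 genes were called higher and 240 lower, which makes 376 of the 19775 genes tested (limma, adjusted p under 0.05). Of these, 49 changed at least 2-fold, 27 up and 22 down.

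Among the 8 largest rises, IL1A rose 7.95-fold and IL1B 4.62-fold, both interleukin-1 genes. The chemokine genes CXCL3 and CXCL1 rose by 2.80 and 2.59 on the log2 scale. VNN1, a pantetheinase gene, rose 7.55-fold, COXFA4L3 rose 6.42-fold, and C3, the central component of complement, rose 5.46-fold. The log2 fold changes of these 7 genes ran from 2.21 (SE 0.19) for IL1B to 2.99 (SE 0.11) for IL1A, and the largest adjusted p among them was 9.01e-04. IL1A has 2 probe sets on the array, of which the dimmer one had a log2 fold change of -0.21 (adjusted p = 0.442). With the mean of both the log2 fold change of IL1A was 1.39, and with the mean of its 2 probe sets that of VNN1 was 2.13 in place of 2.92. The control levels of BCL2A1, IL1A, VNN1, C3 and CXCL3 (5.60, 5.39, 5.24, 6.24 and 6.28) lay below the median of all genes (6.64), where signal over background was not measured, and their folds are lower bounds if those signals are background.

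Among the 8 largest falls, 4 belonged to the list of cholesterol synthesis genes. INSIG1, which holds the sterol sensor in the endoplasmic reticulum, fell by 2.67 on the log2 scale (SE 0.088, adjusted p = 8.04e-06). MSMO1 and HMGCS1, enzymes of cholesterol synthesis, had log2 fold changes of -1.53 and -1.26, and STARD4, a sterol carrier, fell by 1.43. The others besides SCD were TMEM154, which fell by 1.73, TENM1, a teneurin, which fell by 1.57, and AK5, an adenylate kinase, which fell by 1.27. With the mean of their probe sets in place of the brightest one, the log2 fold changes of TENM1 and AK5 were -0.93 and -0.73, and both stayed called. Of all 19775 genes, 3968, or 20.1%, had all 3 arrays of one group above all 3 of the other, where chance gives 10% for 3 against 3.

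**Figure D2:**
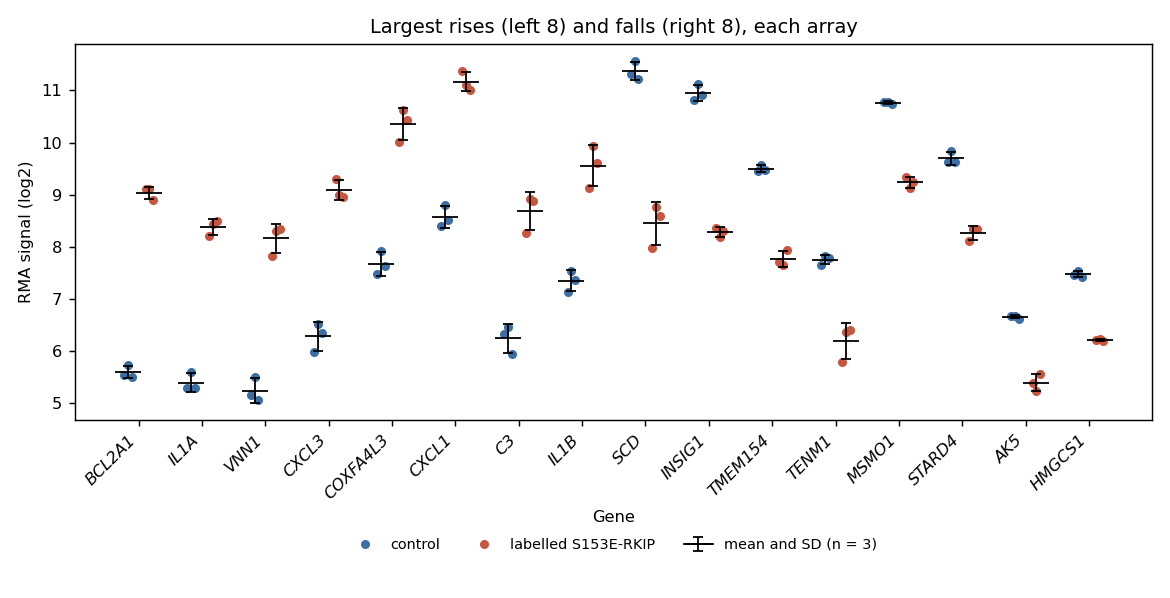
RMA signal (log2) of the 8 genes with the largest rises and the 8 with the largest falls on each array, with the mean and SD of the 3 arrays of each group. Only genes whose groups do not overlap could be chosen, and the means run from 5.60 in control against 9.04 for BCL2A1 to 7.48 against 6.21 for HMGCS1.

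The number of genes called depended on the arrays that entered. Without control replicate 1, 2 or 3 it was 124, 152 or 130, and without S153E-RKIP replicate 2 or 3 it was 171 or 216. The number with at least a 2-fold change stayed between 40 and 56 whichever array was left out.

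Gene lists written before the data were examined were tested next with camera, and 9 of the 26 passed, 4 higher and 5 lower. With a correlation estimated for each list none of the 26 passed, and the smallest adjusted p was 0.0696. Every camera pass below therefore rests on the preset correlation of 0.01. By fry, 6 of these 9 lists also passed and 3 did not. Its adjusted p was 7.57e-04 for NF-kB targets and for cholesterol synthesis, and 0.00355 for chemokines and cytokines. For lung metastasis and for YAP and TAZ it was 0.0112 each, and for blood cell markers 0.0175.

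Of 20 measured NF-kB target genes, 12 rose, none fell and 8 did not pass the test. Adjusted over the list alone, 18 rose. All 20 had a difference above 0, and their mean log2 fold change was 0.94 (SE 0.20). The list passed the set test (adjusted p = 1.77e-25; adjusted p = 0.0696 with an estimated correlation). Beside BCL2A1 and CXCL1, CXCL2 rose by 1.95 (SE 0.13) and CXCL8, the neutrophil attractant interleukin-8, by 1.82 (SE 0.11). CXCL2 was read by a probe set that can pair with several transcripts, and without such probe sets its log2 fold change was 0.56 (adjusted p = 0.00566). The probe set then used had a mean of 4.81 over all arrays, below the median of all genes (6.64), where signal over background was not measured. Of 28 chemokines and cytokines, 9 rose, 18 did not pass the test, and TGFB2 fell (log2 fold change -0.37, SE 0.063; adjusted p = 0.146 without control replicate 1). Adjusted over the list alone, 14 rose and 1 fell. Their mean was 0.77 (SE 0.18; adjusted p = 5.41e-15; adjusted p = 0.117 with an estimated correlation). The lists share 5 genes, CCL20, CXCL1, CXCL2, CXCL8 and IL6, and 8 of the 15 NF-kB targets outside the cytokine list rose. The list of blood cell markers was also higher. Of 19 measured, none was called, 5 had an unadjusted p under 0.05, and 3 rose adjusted over the list alone. Their mean was 0.10 (SE 0.030; adjusted p = 0.0129; adjusted p = 0.183 with an estimated correlation), and without S153E-RKIP replicate 2 the adjusted p was 0.0588. After quantile normalisation again it was 0.166.

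Of 17 measured cholesterol synthesis genes, 12 fell, none rose and 5 did not pass the test. Adjusted over the list alone, 15 fell. Their mean log2 fold change was -0.80 (SE 0.17; adjusted p = 1.14e-25; adjusted p = 0.0696 with an estimated correlation). Beside INSIG1, MSMO1, STARD4 and HMGCS1, DHCR7, a reductase of cholesterol synthesis, fell by 1.09 (SE 0.056). SREBF2, whose product switches on these genes, also fell, by 0.66 (SE 0.080). SREBF2 was named after its value was seen.

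**Figure D3:**
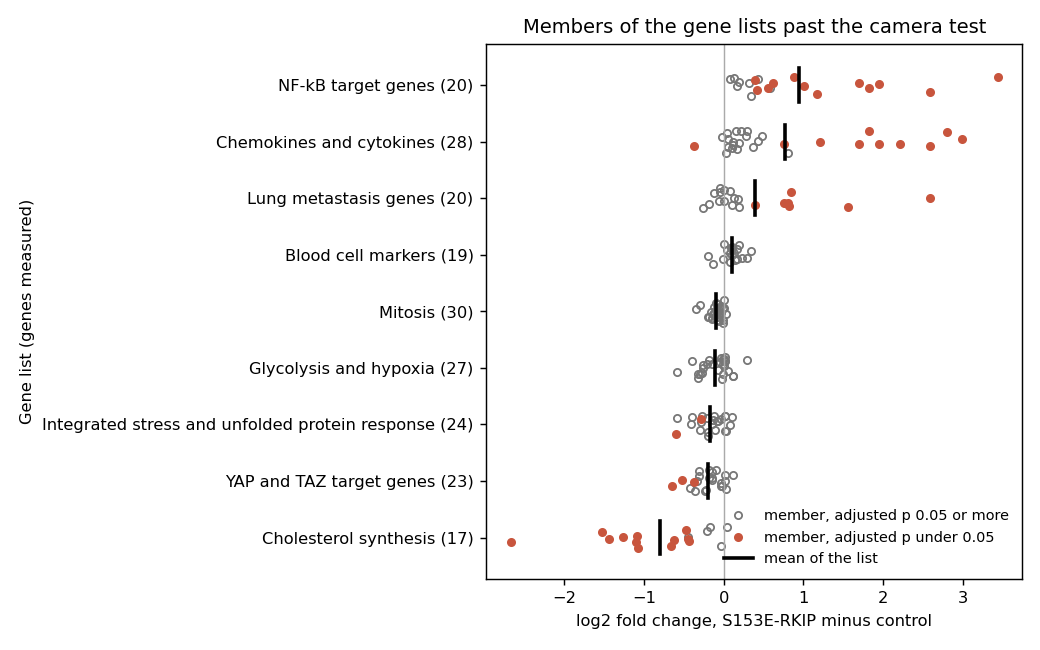
Log2 fold change (S153E-RKIP minus control) of each measured member of the 9 gene lists past the camera test with the preset correlation, with the list mean as a bar and filled points for members called. Called members reach 3.44 among NF-kB target genes and -2.67 among cholesterol synthesis genes, while the lists of mitosis, glycolysis and hypoxia, and blood cell markers hold no called member.

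Lysyl oxidases crosslink collagen and syndecans are cell surface proteoglycans. LOX fell by 0.59 (SE 0.097, adjusted p = 0.0223) and SDC2 fell by 0.84 (SE 0.12, adjusted p = 0.0104), while SDC4 rose by 0.37 (SE 0.062, adjusted p = 0.0255). The other 8 of the 11 measured members were not called, and adjusted over the list alone the count was again 1 rise and 2 falls. The set test gave an adjusted p of 0.399. Leaving out 1 array ended the call of LOX in 5 of 6 cases (adjusted p of 0.124 without control replicate 1, 0.0996 without 2, 0.116 without 3, and 0.0693 and 0.0506 without S153E-RKIP replicates 2 and 3). It ended that of SDC2 without control replicate 1, 2 or 3 (0.0678, 0.0611 and 0.0631) and that of SDC4 in 5 cases (0.133 without control replicate 3), and no direction changed.

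Of 17 bone metastasis genes, 2 fell and 2 rose, and adjusted over the list alone 2 rose and 3 fell. CXCR4, a chemokine receptor for homing to bone marrow, fell by 0.91 (SE 0.10), and FST, which encodes the activin antagonist follistatin, fell by 0.90 (SE 0.095). HBEGF, an EGF receptor ligand, rose by 0.50 (SE 0.059), and MMP1, an interstitial collagenase, rose by 0.40 (SE 0.074). The set test gave an adjusted p of 0.128. Of 20 lung metastasis genes, 7 rose and none fell, and adjusted over the list alone 8 rose. The 7 were CXCL1, MMP1, ID3, TNC, KYNU, an enzyme of kynurenine metabolism (1.56, SE 0.18), IL13RA2 (0.82, SE 0.11) and ID1, an inhibitor of differentiation (0.76, SE 0.082). The list passed (adjusted p = 4.51e-04; adjusted p = 0.253 with an estimated correlation). The call of MMP1 was lost without any 1 of the 6 arrays (adjusted p of 0.166 without control replicate 2), that of TNC without any of 5 and that of ID3 without any of 4 (0.132 and 0.102 without control replicate 1), and that of IL13RA2 without control replicate 1 or 3 (0.0531 and 0.0516). The call of HBEGF was lost with the mean of its 4 probe sets (0.26, adjusted p = 0.0906). Tested on their own, its 2 brighter probe sets were called (0.50 and 0.49, adjusted p = 0.00767 and 0.0189). The dimmer ones were not (0.12 and -0.067).

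Among proteases and inhibitors, MMP1 and PLAUR, the urokinase receptor, rose and TIMP2, a metalloproteinase inhibitor, fell, out of 22 measured. PLAUR rose by 0.49 (SE 0.072) and TIMP2 fell by 0.38 (SE 0.075, adjusted p = 0.0489). Of 29 extracellular matrix genes, only TGFBI (0.70, SE 0.083) and TNC, encoding tenascin-C (0.81, SE 0.13), were called, both higher. Of 21 TGF-beta target genes, 4 rose and none fell. INHBA, which encodes the activin A subunit, rose by 0.91 (SE 0.067) and ID3 by 0.84 (SE 0.13), beside ID1 and TGFBI. Among 19 mesenchymal genes CDH11, encoding cadherin 11, rose by 0.91 (SE 0.16) and SNAI2, encoding Slug, fell by 0.41 (SE 0.081), and among 23 epithelial genes only KRT19 was called, with a fall of 0.48 on its brighter probe set. The adjusted p of the set test was 0.348, 0.320, 0.292, 0.776 and 0.526 for these 5 lists in the order given. By fry, the list of proteases and inhibitors passed as higher (adjusted p = 0.0308), which camera did not show. Adjusted over the list alone, 3 protease genes rose and 1 fell, 2 matrix genes rose, 5 TGF-beta targets rose and 3 fell, 2 mesenchymal genes rose and 1 fell, and 4 epithelial genes fell. SNAI2 and TNC were named after their values were seen. The epithelial median (0.035) and mean (-0.016) differed in sign, and for mesenchymal genes fry pointed up while camera and the mean (-5.9e-04) pointed down. Without control replicate 1 the adjusted p was 0.0912 for PLAUR, 0.213 for TIMP2, 0.168 for CDH11 and 0.205 for SNAI2, and the last 3 calls were lost without at least 5 of the 6 arrays left out in turn. With the mean of its probe sets KRT19 had an adjusted p of 0.246, and after quantile normalisation again TIMP2 had one of 0.0874. Tested on their own, 2 dimmer probe sets of TIMP2 were called lower (-0.44 and -0.42, adjusted p = 0.0245 and 0.0272). The brightest one was not (adjusted p = 0.0724).

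Genes of the Raf-MEK-ERK cascade itself were not called on any of the 14 measured (0 adjusted over the list alone, 1 at an unadjusted p under 0.05, set test adjusted p = 0.320). DUSP6, a phosphatase gene that ERK activity switches on, had a difference of -0.12 (SE 0.076, 95% confidence interval -0.29 to 0.058, adjusted p = 0.488), and of -0.046 without S153E-RKIP replicate 1 (adjusted p = 0.758). Of 25 ERK output genes, HBEGF and IER3, an immediate early gene (0.43, SE 0.082), rose and none fell, while 4 rose and 2 fell adjusted over the list alone. The ERK output list had a mean of -0.028, fry pointed up and camera down, and the set test gave an adjusted p of 0.526. None of 23 LIN28, HMGA2 and let-7 target genes was called, nor was any adjusted over the list alone, while 3 had an unadjusted p under 0.05, and the mean was -0.0033 (SE 0.023, adjusted p = 0.688). IER3 was named after its value was seen, and its adjusted p was 0.178 without control replicate 1.

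Of 23 YAP and TAZ target genes, 3 fell and none rose, and 9 fell adjusted over the list alone. ANKRD1 fell by 0.65 (SE 0.11), RBMS3, an RNA-binding protein gene, by 0.52 (SE 0.085) and TGFB2 fell by 0.37. The list mean was -0.20 (SE 0.040; adjusted p = 1.46e-07; adjusted p = 0.117 with an estimated correlation). Of 24 genes of the integrated stress and unfolded protein response, HERPUD1 fell by 0.60 (SE 0.089) and PHGDH, an enzyme of serine synthesis, by 0.29 (SE 0.057, adjusted p = 0.0487), and 5 fell adjusted over the list alone. That list had a mean of -0.17 (adjusted p = 2.55e-05; adjusted p = 0.253 with an estimated correlation and 0.0570 by fry). Each of these 5 calls was lost without any of at least 4 arrays. Without control replicate 3 the adjusted p was 0.130 for ANKRD1 and 0.201 for PHGDH, and without control replicate 1 it was 0.127 for RBMS3, 0.146 for TGFB2 and 0.0856 for HERPUD1. With the mean of their probe sets the log2 fold change was -0.33 for HERPUD1 and -0.31 for RBMS3, both still called, and -0.29 for TGFB2 (adjusted p = 0.0561), and after quantile normalisation again PHGDH had an adjusted p of 0.0709.

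None of 30 mitosis genes and none of 27 glycolysis and hypoxia genes was called, over all genes or adjusted over the list alone, although both lists passed the set test as lower. At an unadjusted p under 0.05 there were 6 and 7. Mitosis had a mean of -0.095 (SE 0.016; adjusted p = 5.68e-05; adjusted p = 0.398 with an estimated correlation and 0.0641 by fry), and glycolysis and hypoxia a mean of -0.10 (SE 0.037; adjusted p = 0.0233; adjusted p = 0.666 with an estimated correlation and 0.432 by fry). The mean of the glycolysis and hypoxia list was -0.061 without control replicate 2 (adjusted p = 0.173), -0.022 without S153E-RKIP replicate 1 (adjusted p = 0.513) and -0.17 without S153E-RKIP replicate 2. Its adjusted p was 0.138 after quantile normalisation again, and 0.326 and 0.187 with only genes above the median level or above 6 on at least 3 arrays. No gene was called among 29 of S phase, 22 of ribosome biogenesis, 16 of heat shock, or 19 markers of fibroblasts, osteoblasts and endothelium (set test adjusted p = 0.648, 0.181, 0.115 and 0.461). At an unadjusted p under 0.05 these 4 lists had 0, 1, 5 and 2 members, and adjusted over the list alone 1 heat shock gene rose and 4 fell, with 0 in the other lists. Elsewhere CDKN1A, the p53 target encoding p21, rose by 0.41 (SE 0.068), SLC7A11, the cystine transporter gene of the NRF2 list, fell by 0.74 (SE 0.077), and IFIT3 of the interferon response fell by 0.65 (SE 0.083). Each was the only called member of 19, 23 and 30 measured, and the adjusted p of the set test was 0.526, 0.489 and 0.249. Adjusted over the list alone, 1 p53 target rose, 1 NRF2 target fell and 3 interferon genes fell. Without control replicate 1 the adjusted p was 0.129 for CDKN1A and 0.0576 for IFIT3.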

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

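The tests for blood cells, for near-identical chemokine sequences and for a change of scale in the NF-kB and cholesterol lists were chosen after the result was seen, as was the removal of the intensity trend.

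Among the 13522 probe sets without a gene of their own in the annotation, which no gene comparison used, 27 were called higher and 54 lower. The largest difference was that of probe set 1555623_at, at 3.36 ± 0.040 (SD, n = 3) on the control arrays and 11.47 ± 0.31 (SD, n = 3) on the arrays labelled S153E-RKIP, a difference of 8.11 (SE 0.14, adjusted p = 7.04e-08). Probe set 233847_x_at followed with 3.14 ± 0.049 and 8.18 ± 0.19 (SD, n = 3 each), a difference of 5.04 (SE 0.096, adjusted p = 1.14e-07). Both were higher on 3 of 3 arrays, and their control levels lay at the 1.55 and 0.0476 percentile of all probe sets. Both differences are lower bounds if those control signals are background, which was not measured. Whether they read transcripts of the cells or parts of the introduced construct is not given in the sources used here. The deepest falls among these probe sets were -2.68 for 223839_s_at and -2.46 for 227759_at. All 4 are unnamed here.

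The rise of NF-kB target genes and cytokines may come from the treatment, from other cells or from the arrays. White blood cells as the whole cause are argued against by a median log2 fold change of 0.097 over 18 monocyte and neutrophil genes against 0.57 in the NF-kB list, with none called and 3 at an unadjusted p under 0.05, and by LYZ and S100A8, abundant in such cells, at log2 fold changes of 0.10 (SE 0.068) and -0.019 (SE 0.094). A small share of such cells stays open, since 14 of the 18 lay above 0, their list passed the set test as higher (adjusted p = 0.0195; adjusted p = 0.0820 with an estimated correlation), 10 are also among the blood cell markers, HLA-DRA and CTSS rose, and the cells themselves express SRGN, ARHGDIB and LAPTM5 strongly (13.23, 11.74 and 8.88 in control). Chemokines read several times are argued against by a mean of 0.75 (SE 0.21) without the chemokines, with 9 of 16 higher, and a change of scale by a list mean of 0.94, above the highest of 10000 matched lists (0.25). An effect of the introduced construct stays open as a hypothesis, as does any difference in culture or RNA handling between the groups that the labels do not record.

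The fall of cholesterol synthesis genes may likewise come from the treatment or from the arrays. A change of scale with intensity is argued against by the list mean of -0.80, below the lowest of 10000 matched lists (-0.30). A sterol surplus that also switches on LXR predicts a rise of LXR target genes. The 10 measured did not rise as a set, with a median of -0.18 (SE of the mean 0.061) and none called higher. SREBF1 and LPCAT3 were called lower, but not without control replicate 1 (adjusted p of 0.159 and 0.124) or with the mean of their probe sets (0.0630 and 0.307), SREBF1 is also in the fatty acid list, and ABCA1 was measured poorly (-0.20, SE 0.40). ABCG1 and ABCG4 had control levels of 5.87 and 4.91, below the median of all genes (6.64). With these limits the LXR target genes do not decide on a sterol surplus. An effect of the treatment stays open, as do such a surplus and any difference in culture between the groups that the labels do not record.

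The mitosis, glycolysis and hypoxia, and blood cell marker lists, with no member called, may have passed through a change of scale. Over 5 bins of genes ranked by intensity the median log2 fold change ran from -0.048 to 0.064. It was -0.024 in the brightest bin, where the mean levels of mitosis and of glycolysis and hypoxia lay, and 0.064 in that of the blood cell markers. Against the matched lists, mitosis and glycolysis and hypoxia lay below the 95% range (from -0.081 and -0.079) but above the lowest (-0.16 and -0.19). Blood cell markers lay inside that range (up to 0.11). With the intensity trend removed, mitosis still passed camera, with a mean of -0.065 (SE 0.015, adjusted p = 0.0109) against -0.095 (SE 0.016) before. That pass rests on the preset correlation of 0.01, while the estimated correlation of the list was 0.19. Before the trend was removed, the list did not pass with an estimated correlation (adjusted p = 0.398) or by fry (0.0641). The test therefore does not decide whether a change of scale is the whole cause for mitosis. Glycolysis and hypoxia no longer passed (adjusted p = 0.117), but its mean moved from -0.10 (SE 0.037) to -0.082 (SE 0.035), by less than its spread, so the lost call does not decide. The mean of the blood cell markers moved from 0.10 (SE 0.030) to 0.060 (SE 0.032), with an adjusted p of 0.117. For all of these lists a change of scale and a small change in the genes both stay open.

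The groups can be split in only 10 ways, too few for a share under 0.05. The real split called 376 genes and 49 with at least 2-fold change, and it was the only 1 of the 10 to reach either, since the highest of the others was 0 for both. For gene lists past the set test, 2 of the 10 splits reached the real value of 9, and the highest of the others was 12, for control replicates 1 and 3 with S153E-RKIP replicate 1 against the rest.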

How the results depend on the processing

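The removal of the intensity trend was added after seeing the data; all other alternatives were planned. The count of 376 genes became 600 with eBayes trend and robust estimation, 574 over 54613 probe sets tested on their own, and 147 at an adjusted p under 0.01, where the stricter threshold is the cause. It ran from 124 to 303 with 1 array left out, where fewer samples are at hand, and stayed within 1.5 times under the other 9 alternatives. The 49 genes with at least 2-fold change became 104 on probe sets tested on their own, and 40 to 56 with 1 array left out. On their own, several probe sets can stand for a gene, and the 13522 probe sets without a gene of their own also enter. The 9 gene lists became 0 with an estimated correlation, 7 by fry and 8 to 10 with 1 array left out. By fry, 3 of the 9 calls were lost, those of mitosis (adjusted p = 0.0641), glycolysis and hypoxia (0.432) and integrated stress and unfolded protein response (0.0570). Proteases and inhibitors, not past camera, passed by fry as higher (0.0308). Glycolysis and hypoxia also lost its call after quantile normalisation again (0.138), with the trend removed (0.117) and under both dim-gene filters (0.326 and 0.187), with adjusted p from 2.19e-04 to 0.513 over the camera settings with the preset correlation. PEBP1 stayed below 0 and uncalled throughout, from -0.13 to -0.066 with 1 array left out. HMGA2 stayed uncalled, but its sign turned to 0.011 after quantile normalisation again and 0.022 with the trend removed, and it ran from -0.059 to 0.0034 with 1 array left out; all lie within its confidence interval, and the cause was not tested. With a replicate block 332 genes were called, 276 of them shared with the 376, and 5 named genes were not called, SDC4, TIMP2, PHGDH, CDKN1A and TGFB2 (adjusted p of 0.0585, 0.0800, 0.0811, 0.0538 and 0.0647). Whether the replicate numbers pair the arrays cannot be told from so few arrays. With the group means removed, same-numbered arrays correlated at 0.13, 0.26 and -0.044, and differently numbered ones from -0.27 to 0.13. Not every array correlated best with its own number. Of 44 called named genes 28 were called in all 6 fits that leave 1 array out, and no named gene but HMGA2 changed direction. Besides PEBP1 and HMGA2, 45 genes were named, and of these 3 calls were lost with the mean of the probe sets (HBEGF, KRT19 and TGFB2), 3 on probe sets tested on their own (MMP1, TIMP2 and PHGDH), 3 with the trend removed (TIMP2, PHGDH and TGFB2), 2 after quantile normalisation again (TIMP2 and PHGDH) and 1 without _x_at probe sets (PHGDH). Over 17 alternatives TIMP2, PHGDH and TGFB2 stayed called in 7, 6 and 8. Blood cell markers no longer passed after quantile normalisation again or with the trend removed (adjusted p = 0.166 and 0.117, from 1.70e-04 to 0.166 over the camera settings with the preset correlation). AK5 fell under the filter on the median level and has no value there. Signal over background limits what can be said of dim genes, and was not measured here.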

Other observations

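The lists and tests in this part were chosen after the called genes were seen, and the tests were written before the values of the other members were looked at.

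Beside cholesterol synthesis, genes of fatty acid synthesis were lower on the arrays labelled S153E-RKIP. Of 12 measured, 7 fell and none rose: SCD, LPIN1, which encodes a phosphatidate phosphatase (-1.15, SE 0.10), FASN, encoding fatty acid synthase (-0.95, SE 0.095), FADS2 (-0.72, SE 0.082), SREBF1 (-0.60, SE 0.11), ACACA, encoding acetyl-CoA carboxylase (-0.44, SE 0.059), and ACLY (-0.31, SE 0.054). SCD, FASN and LPIN1 were known before the test. Of the other 9 members, 4 were called lower, as the hypothesis that both groups of lipid genes fall together predicts. The list was chosen after the called genes were seen, so this count is not independent support. The set test, run with SCD, FASN and LPIN1 included, gave an adjusted p of 4.74e-12 with the preset correlation (adjusted p = 0.0575 with an estimated correlation), over 5 lists. Without control replicate 1 the adjusted p was 0.159 for SREBF1 and 0.0690 for ACACA, and without control replicate 2 it was 0.139 for ACLY. With the mean of their probe sets it was 0.0630 for SREBF1 and 0.0994 for ACACA.

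All 19 measured genes of antigen presentation had a difference above 0, with a mean of 0.36 (SE 0.083). Blood cell markers (mean 0.10, adjusted p = 0.0129, and 0.183 with an estimated correlation) and monocyte and neutrophil genes (14 of 18 above 0, adjusted p = 0.0195, and 0.0820 with an estimated correlation) were also higher, with no gene of either called over all genes. HLA-DRA, a class II chain (1.03, SE 0.17), CTSS, encoding cathepsin S (1.51, SE 0.14), and PSMB9, an immunoproteasome subunit (0.29, SE 0.054), were called, and CD74 missed the threshold (0.64, SE 0.14, adjusted p = 0.0607). HLA-DRA and CTSS were known before the test. Of the 19, 12 rose adjusted over the list alone. The set test, run with HLA-DRA and CTSS included, gave an adjusted p of 4.74e-12 (adjusted p = 0.0575 with an estimated correlation). Besides HLA-DRA and CTSS 1 member, PSMB9, was called over all genes, too few under the test as written to decide whether the antigen presentation genes rise together with HLA-DRA and CTSS. Of 13 acute phase and complement genes, C3, SERPINA1, encoding alpha-1 antitrypsin (1.65, SE 0.20), CEBPD (1.03, SE 0.17) and PTX3, encoding pentraxin 3 (0.48, SE 0.068), were higher. Of the 13, 5 rose and 1 fell adjusted over the list alone. The set test, run with C3, SERPINA1 and CEBPD included, gave an adjusted p of 0.00239 (adjusted p = 0.0969 with an estimated correlation). Besides C3, SERPINA1 and CEBPD, which were known before the test, PTX3 was the only 1 called, which leaves open whether they rise together with C3, SERPINA1 and CEBPD. SERPINA3 (0.0047, SE 0.061) and LCN2 (0.17, SE 0.074, adjusted p = 0.326) were not called. With 1 array left out the adjusted p reached 0.134 for HLA-DRA (without S153E-RKIP replicate 2) and 0.161 for PSMB9 (without control replicate 2), and without control replicate 1 it was 0.132 for CEBPD, 0.0678 for PTX3 and 0.0587 for SERPINA1.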
